A study of Mus musculus with 12 samples.

How the data were processed

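RNA sequencing of 12 libraries from C57BL/6 mouse bone marrow stromal cells marked with GFP was used, 3 libraries in each of the groups NC, HOMING, BM and TUMOR. Per the labels, cells were sorted and frozen, RNA was taken with Trizol, and libraries were made with the Illumina TruSeq RNA preparation. No gate or purity of the sort is given in the sources used here. The authors mapped reads with Bowtie 0.12.2 to genome build mm8, and the program that counted reads is not given in the sources used here. Groups were taken from the sample titles, and replicate numbers were not used to pair samples.

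Each library has 1 table of transcripts with a value above 0. In these deposited tables the authors give expected counts, which are estimated reads per transcript without normalization, and FPKM, which the authors scaled to transcript length and to the mapped fragments of a library and rounded to 2 decimals. Both columns were checked on the values: expected counts are fractional and differ between libraries in their sum, and the lowest FPKM listed is 0.01. Transcripts not listed were set to 0. Expected counts and FPKM were summed per gene, giving 21001 genes. Of 19679 Entrez numbers, 19629 matched a symbol in the reference gene table, which was used for symbols alone, so no coordinates are given. The 1322 genes listed without an Entrez number took 2.08 to 2.65% of the counts. The 10 most abundant genes took 4.77 to 5.38% of the counts of a library.

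Library totals were 43232145 to 46166519 expected counts. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 12314. Rounded gene counts were scaled by TMM, with factors of 0.929 to 1.039, and fitted in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood model of the 4 groups, followed by a two-sided quasi-likelihood F-test for each of 6 comparisons. P-values were adjusted by Benjamini and Hochberg over the 12314 genes of a comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. This test was chosen after the files were seen, because they hold counts. The test written earlier, limma 3.58.1 on log2(FPKM + 1), is given among the alternatives. The comparisons, the gene lists, the rule for naming genes and the other thresholds were fixed before the data were examined.

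In a test on simulated data, 100 genes changed 3-fold and 100 changed 6-fold were added to each comparison. EdgeR recovered 100% of both sets with 0 false calls, and limma recovered 93 to 96% and 99 to 100%. For a gene with 0 counts in a group, fold changes are bounds against a floor of 3 counts over the group. For 1 to 3 counts the ratio of counts scaled by library is given with an exact 95% interval.

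The 32 lists covered stromal identity, osteoblast, adipocyte, chondrocyte and niche genes, markers of neutrophils, macrophages, B cells, T and NK cells, red cells, megakaryocytes, endothelium, epithelium, osteoclasts and skeletal muscle, chemokines, suppressive mediators, matrix, contractile and protease genes, cell cycle, interferon, NF-kB, hypoxia, oxidative phosphorylation, ribosomal, unfolded protein, immediate early, antigen presentation, p53, migration and housekeeping genes. Lists with at least 4 measured members were tested with camera in limma at a preset correlation of 0.01, two-sided, with p adjusted over the 150 list tests. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move one way on balance and does not compare a list with other genes.

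The text names, per comparison, the 6 largest rises and 6 largest falls (10 and 10 in BM against HOMING) among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of both groups. Predicted genes, olfactory and vomeronasal receptors and immune receptor segments were left out. Up to 4 members of a described list were those with the smallest adjusted p, or the highest FPKM where none was called. In BM against NC and TUMOR against HOMING fewer genes are named. Principal components and Pearson correlations used log2(FPKM + 1) of the tested genes.

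Alternatives were DESeq2 1.42.0, limma with a pseudocount of 1 or 0.1 FPKM and with quantile normalization, scaling by median ratios or by library size, no filter, only genes with a mean of at least 1 FPKM in NC, the transcript with the highest mean FPKM in place of gene sums, fits on the compared groups alone, no variance trend, a replicate block, no minimum fold change, and leaving out each library in turn. DESeq2, limma with a pseudocount of 1, scaling by library size and the restriction to genes expressed in NC were added after the data were seen. Of the lists made after the data were seen, 1 is not reported here. Other splits of the 6 libraries of each comparison and 100 regroupings of all 12 were refitted. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.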

Results

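Marked stromal cells were compared in 4 states, each with 3 sequenced libraries. NC stands for mouse bone marrow stromal cells carrying green fluorescent protein (GFP) in primary culture. HOMING stands for GFP cells sorted from the marrow of mice that had received these cells alone under the skin. BM stands for GFP cells sorted from the marrow of mice given the same cells together with Lewis lung carcinoma cells, a mouse lung tumour line carrying a red fluorescent protein. TUMOR stands for GFP cells sorted from the injection site of mice given both. The series title concerns stromal cells educated by cancer, the niche that precedes metastasis and the expansion of suppressive myeloid cells, so BM against HOMING was taken as the leading comparison. The labels do not say whether the 3 replicates of a group are separate animals or cultures, so each p-value measures the spread between these samples alone, which may be technical.

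Each library held 43232145 to 46166519 expected counts, and 12314 genes passed the expression filter. Levels are given as mean FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) ± SD with n = 3 libraries per group. Fold changes are log2 values ± SE from edgeR, positive when the group named first is higher, and a gene is called, and said to rise or fall, when its p adjusted over all 12314 genes was under 0.05 and its level changed at least 2-fold. The 12 libraries fell into their 4 groups. Pearson's r between libraries, computed across genes that are not independent replicates, was 0.992 to 0.999 over the 12 pairs within groups and 0.895 to 0.968 over the 54 pairs between groups. The first principal component held 48.2% of the variance and set HOMING apart, the next held 32.7% and set TUMOR apart, and the one after it held 14.5% and set BM apart.

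**Figure D1:**
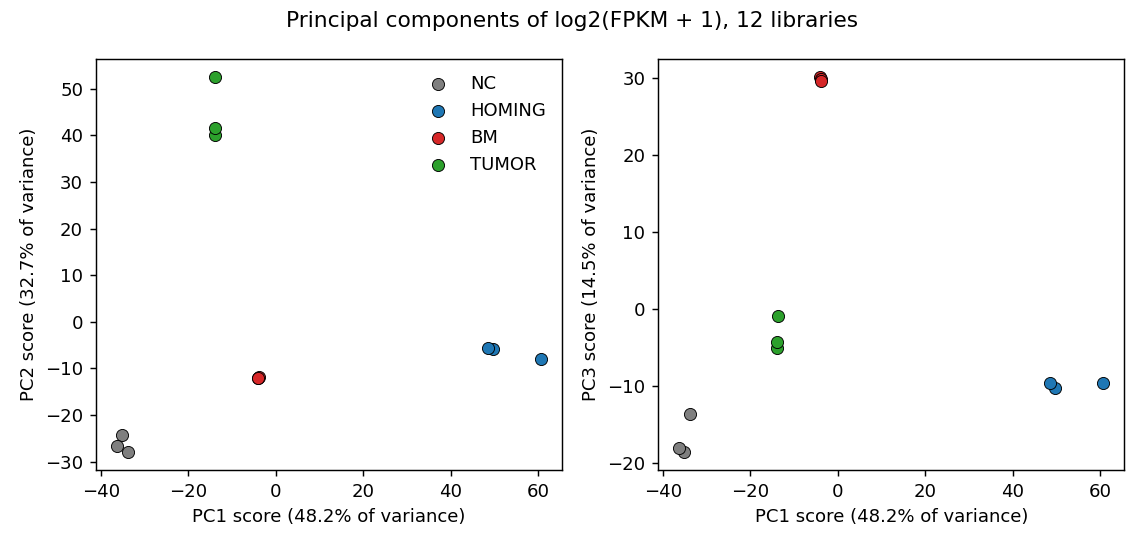
Principal components of log2(FPKM + 1) over 12314 genes, with component 1 (48.2% of the variance) on the x axis against component 2 (32.7%) at left and component 3 (14.5%) at right. Each point is 1 of the 12 libraries, coloured by group, and the libraries of a group lie together.

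Libraries of GFP-sorted marrow cells from tumour-bearing mice had higher levels on the unfolded protein response list than those from mice given stromal cells alone. They had lower levels on the blood-cell lists. Camera called these lists at its preset correlation only. With an estimated correlation its adjusted p was 0.169 for the unfolded protein response and 0.239 to 0.278 for the blood-cell lists. Chac1 rose from 24.0 ± 1.17 to 231 ± 6.79 FPKM (log2 3.30 ± 0.09). Chac1 (Entrez 69065) encodes an enzyme that degrades glutathione and is induced by the unfolded protein response. Of the 13 unfolded protein response genes, 0 were called higher or lower in BM than in NC. The neutrophil chemoattractant Cxcl1 (Entrez 14825) rose from 492 ± 18.3 to 1191 ± 70.5 FPKM (log2 1.31 ± 0.15). The calprotectin subunit S100a8 (Entrez 20201), a product of granulocytes, fell from 834 ± 191 to 21.3 ± 3.03 FPKM (log2 -5.26 ± 0.17), and its partner S100a9 fell from 800.4 ± 161 to 19.8 ± 1.85 FPKM (log2 -5.31 ± 0.19). In the test over all genes 1280 genes were called, 457 higher and 823 lower in BM. Cxcl1, S100a8 and S100a9 were chosen after their values were seen.

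The 10 largest rises were in genes of varied function. The growth arrest gene Gadd45a rose from 30.1 ± 1.03 to 264 ± 16.2 FPKM (log2 3.16 ± 0.06), the stress-induced transcription factor Atf3 rose from 13.5 ± 1.60 to 97.3 ± 1.04 FPKM (log2 2.88 ± 0.08), and Sesn2 rose from 8.997 ± 0.399 to 51.4 ± 1.77 FPKM (log2 2.54 ± 0.09), whose product restrains mTORC1 signalling. Txnip, which encodes a thioredoxin-binding protein, rose from 22.4 ± 2.63 to 159 ± 4.63 FPKM (log2 2.86 ± 0.09). Tnfaip6, which encodes the hyaluronan-binding protein TSG-6 secreted by stromal cells, rose from 2.93 ± 0.117 to 27.0 ± 2.32 FPKM (log2 3.24 ± 0.10), and the lysosomal membrane gene Tmem74 rose from 1.14 ± 0.116 to 10.03 ± 0.456 FPKM (log2 3.16 ± 0.14). The other members were homeobox genes of the X-linked Rhox cluster, which act in reproductive tissue. Rhox5 rose from 4.21 ± 0.390 to 43.6 ± 0.615 FPKM (log2 3.40 ± 0.25), Rhox2d rose from 0.683 ± 0.0929 to 7.97 ± 0.531 FPKM (log2 3.55 ± 0.28) and Rhox2h rose from 0.563 ± 0.0808 to 5.45 ± 0.264 FPKM (log2 3.31 ± 0.36), the last pair being paralogs whose reads are hard to tell apart. Rhox5 stood at 185 ± 71.9 FPKM in TUMOR and 0.133 ± 0.119 FPKM in NC, so BM and HOMING lay between these. Gadd45a and Sesn2 are among the 12 p53 targets, of which 0 were called higher and 1 lower in BM than in NC. In HOMING against NC 1 of the 12 was higher and 3 lower. Chac1 is among the 13 unfolded protein response genes, of which 0 were called in BM against NC. Gadd45a, Sesn2 and Chac1 thus rose over HOMING without a called rise over the cultured cells.

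The 10 largest falls were red blood cell genes, interferon-induced genes and a myeloid gene. Alpha-globin Hba-a1 fell from 1250.0 ± 389 to 0.977 ± 0.0874 FPKM (log2 -10.31 ± 0.28), and its paralog Hba-a2 fell from 247 ± 79.0 to 0.650 ± 0.0889 FPKM (log2 -8.49 ± 0.30). Among beta-globins Hbb-bs fell from 923 ± 251 to 1.13 ± 0.103 FPKM (log2 -9.65 ± 0.27) and Hbb-bt fell from 139.8 ± 40.3 to 0.280 ± 0.229 FPKM (log2 -8.88 ± 0.36), with reads shared between such paralogs. Alas2, the haem synthesis enzyme of red cell precursors, fell from 13.8 ± 4.08 to 0.147 ± 0.0208 FPKM (log2 -6.54 ± 0.26), and Slc4a1, the anion exchanger of the red cell membrane, fell from 8.26 ± 2.65 FPKM to 5 counts over the 3 BM libraries. The Schlafen genes Slfn4 and Slfn1 fell by 7.99 ± 0.26 and 6.62 ± 0.29 on the log2 scale, the antiviral gene Rsad2 fell by 6.31 ± 0.24 and the prokineticin gene Prok2 fell by 6.12 ± 0.36. Adjusted p over these 20 genes ranged from 5.21e-12 to 5.84e-06 in edgeR. Without BM replicate 2 the log2 change of Hbb-bt was -9.74, and without BM replicate 3 those of Slc4a1 and Prok2 were -10.51 and -6.74.

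Genes of marrow blood cells fell together. Of the neutrophil and granulocyte precursor markers 0 of 16 rose and 16 fell (camera adjusted p 7.66e-10), and of the monocyte and macrophage markers 0 of 12 rose and 10 fell (camera adjusted p 2.74e-06). Among erythroid markers 0 of 6 rose and 6 fell (camera adjusted p 7.04e-06), and among megakaryocyte markers 0 of 5 rose and 4 fell (camera adjusted p 0.00406). The pan-leukocyte antigen gene Ptprc (CD45), chosen after its values were seen, had 5193 counts over the HOMING libraries, 212 over BM, 5 over TUMOR and 2 over NC. An estimated correlation gave these 4 lists adjusted p of 0.239 to 0.278. Adjusted over the list alone, each list gave the same counts of called members as over all genes in this comparison. Camera called 61 of 150 list tests over the 6 comparisons with its preset correlation and 0 with an estimated correlation.

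**Figure D2:**
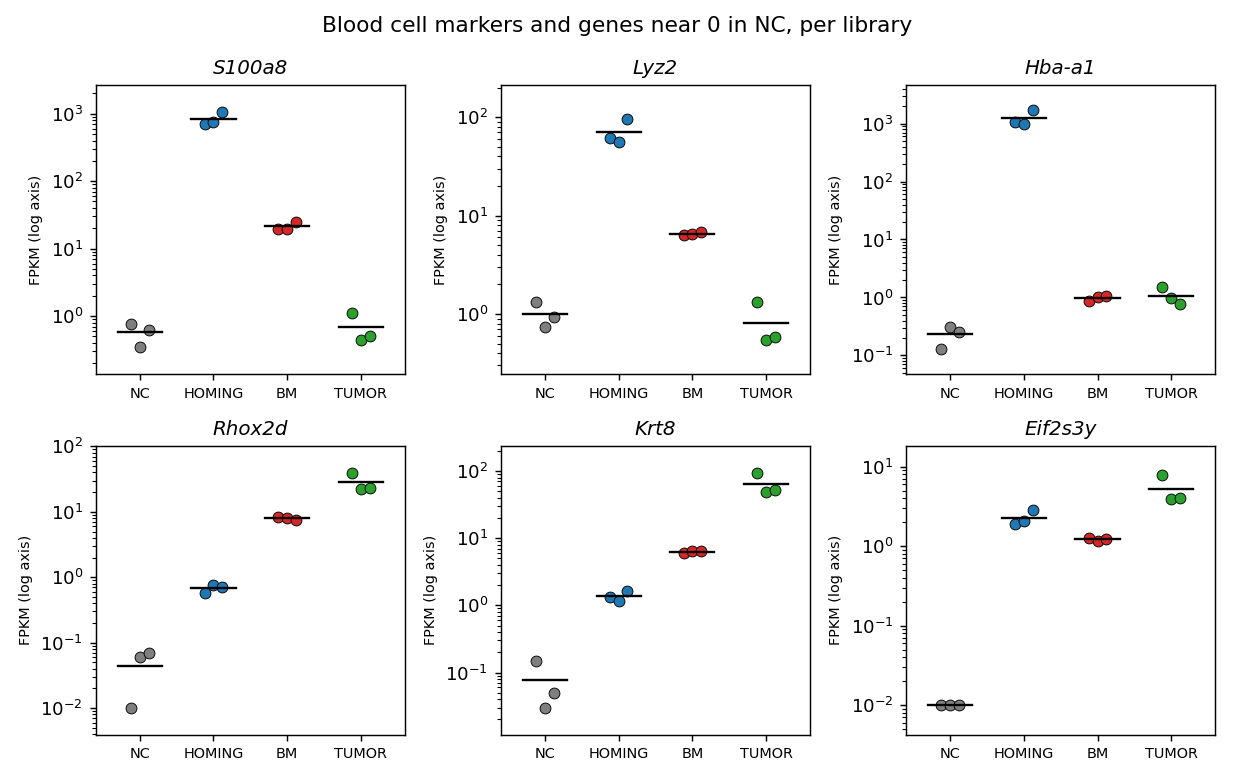
FPKM on a log axis in each of the 12 libraries for the blood-cell genes S100a8, Lyz2 and Hba-a1 and for Rhox2d, Krt8 and Eif2s3y, by group on the x axis. Points are libraries, lines are group means, values under 0.01 FPKM are drawn at 0.01, and the blood-cell genes peak in HOMING while the other 3 peak in TUMOR.

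Groups of immune genes fell alongside these blood markers. Of the interferon response genes 0 of 20 rose and 18 fell (camera adjusted p 8.09e-12): the ubiquitin-like modifier Isg15 fell from 50.3 ± 7.37 to 1.84 ± 0.392 FPKM (log2 -4.74 ± 0.18) and the transcription factor Irf7 fell from 33.1 ± 7.34 to 1.33 ± 0.157 FPKM (log2 -4.61 ± 0.19). Of the antigen presentation genes 0 of 13 rose and 8 fell (camera adjusted p 1.50e-06): the peptide transporter Tap1 fell from 11.9 ± 2.92 to 1.11 ± 0.0651 FPKM (log2 -3.38 ± 0.19), and the class II invariant chain Cd74 fell from 26.0 ± 7.25 to 2.05 ± 0.310 FPKM (log2 -3.64 ± 0.26). Of the migration receptors and integrins 0 of 14 rose and 9 fell (camera adjusted p 0.0052), led by the leukocyte integrin Itgam, which fell from 39.9 ± 14.2 to 2.37 ± 0.0513 FPKM (log2 -4.04 ± 0.21), and the leukocyte selectin ligand Selplg, which fell from 7.03 ± 1.86 to 0.343 ± 0.0569 FPKM (log2 -4.31 ± 0.24). Adjusted p over these 3 lists was 0.25 to 0.348 once the correlation was estimated. Over the 11061 genes with a mean of at least 1 FPKM in NC, the median log2 change of the migration and integrin list was 0.081 with adjusted p 0.864, so no fall of that list was called among genes expressed in culture, while the interferon response and antigen presentation lists stayed called.

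The unfolded protein response list moved up, with 5 of 13 genes higher and 0 lower (camera adjusted p 0.000107). In BM against NC 0 of these 13 were higher and 0 lower (median log2 change -0.20, camera adjusted p 0.154). The pro-apoptotic transcription factor Ddit3 (Entrez 13198) rose from 52.2 ± 3.18 to 186 ± 9.05 FPKM (log2 1.86 ± 0.08), the pseudokinase Trib3 rose from 18.0 ± 0.642 to 92.9 ± 1.98 FPKM (log2 2.40 ± 0.07), and Herpud1, of endoplasmic reticulum protein degradation, rose from 42.2 ± 1.19 to 156 ± 1.000 FPKM (log2 1.91 ± 0.05). Chac1 and the asparagine synthetase gene Asns (log2 1.04 ± 0.04, chosen after its values were seen) were the other risers. The 8 members not called were Hspa5, Hsp90b1, Pdia4, Calr, Dnajb9, Sdf2l1, Atf4 and Xbp1. The call of the list thus does not extend to each of its genes. Matrix proteases and inhibitors shifted upward with 5 of 19 higher and 1 lower (camera adjusted p 0.0197). Stromelysin Mmp3 (Entrez 17392) rose from 57.8 ± 7.41 to 310.2 ± 9.88 FPKM (log2 2.46 ± 0.15), while the gelatinase Mmp9, also made by neutrophils, fell from 14.5 ± 4.71 to 2.86 ± 0.254 FPKM (log2 -2.31 ± 0.27). Adamts1 rose from 7.42 ± 0.112 to 34.0 ± 1.39 FPKM (log2 2.23 ± 0.14), Adamts4 rose from 1.52 ± 0.128 to 3.42 ± 0.197 FPKM (log2 1.20 ± 0.19), and Mmp2 and Mmp10, chosen after their values were seen, rose by log2 1.13 ± 0.33 and 1.21 ± 0.27. For these 2 lists the estimated correlation gave adjusted p of 0.169 to 0.462.

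Myeloid-recruiting chemokines and cytokines split by gene: 4 of 19 rose and 9 fell, the median log2 change was 0.26 and the mean -0.74, and the list was not called (camera adjusted p 0.923). The risers were Cxcl1, Lif (log2 1.62 ± 0.24), Csf2 (log2 1.02 ± 0.41) and Vegfa (log2 1.07 ± 0.04). The call of Csf2 (adjusted p 0.0494 in edgeR) ended when any 1 BM or HOMING replicate was left out (0.0857 to 0.116). Among the 4 most abundant members in BM, Ccl2 and Cxcl5 reached 2412 ± 127 and 859 ± 57.8 FPKM in BM against 1249 ± 45.2 and 635 ± 19.3 FPKM in HOMING and did not change by the 2-fold minimum; without BM replicate 1, Ccl2 passed it at log2 1.01. The monocyte products Tnf fell from 45.1 ± 12.9 to 3.29 ± 0.0985 FPKM (log2 -3.75 ± 0.17) and Ccl4 fell from 117 ± 30.7 to 9.20 ± 0.168 FPKM (log2 -3.65 ± 0.20), and the granulocyte growth factor Csf3 fell from 58.4 ± 15.5 to 6.11 ± 0.569 FPKM (log2 -3.23 ± 0.18), in the direction of the blood markers. Among immunosuppressive mediators 1 of 14 rose and 6 fell, not called as a list (camera adjusted p 0.188): Cd274 fell from 20.6 ± 4.84 to 0.993 ± 0.123 FPKM (log2 -4.34 ± 0.18), while the prostaglandin synthase gene Ptgs2 rose (log2 1.18 ± 0.22). Lif, Csf2, Ccl2, Cxcl5 and Ptgs2 were chosen after their values were seen.

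**Figure D3:**
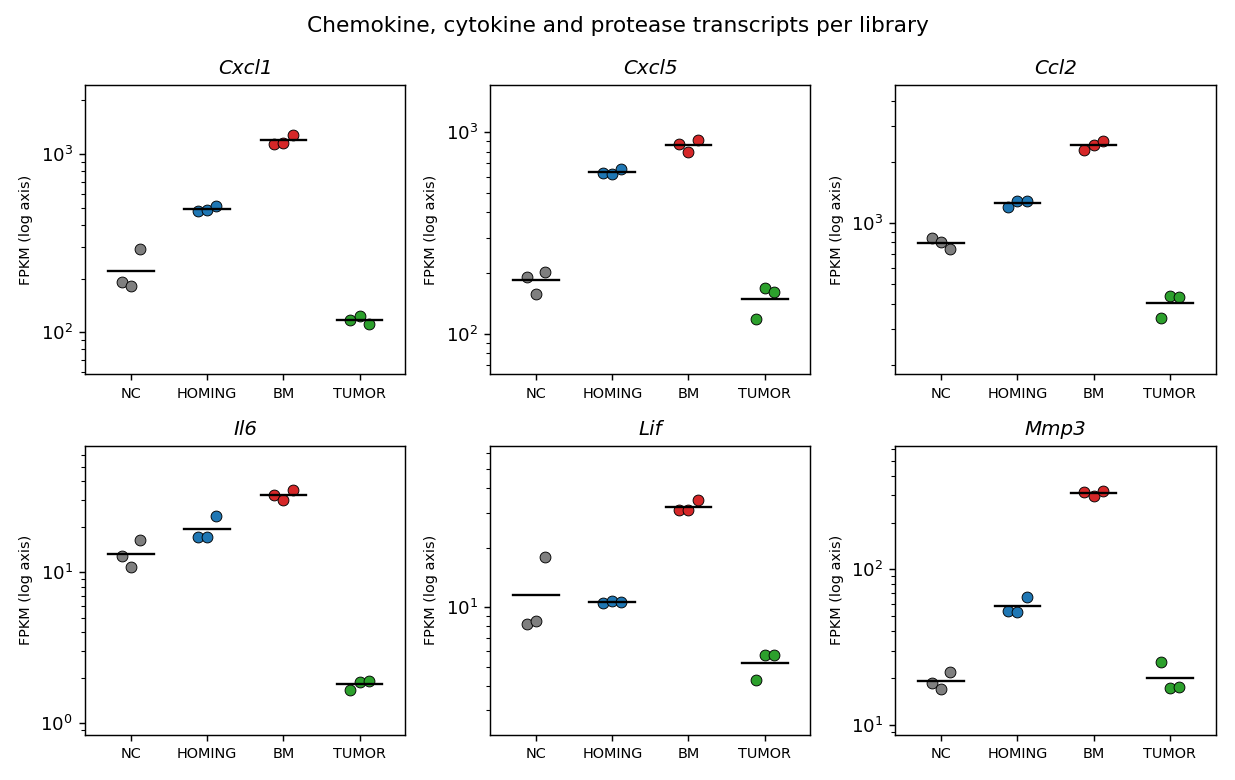
FPKM on a log axis in each of the 12 libraries for Cxcl1, Cxcl5, Ccl2, Il6, Lif and Mmp3, by group on the x axis. Points are libraries, lines are group means, and each of the 6 genes has its highest mean in BM.

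The other lists were not called in BM against HOMING. Risers, fallers and camera adjusted p were 2, 0 and 0.299 for the 16 measured genes of mesenchymal stromal identity, 0, 1 and 0.493 for 6 osteoblast markers, 1, 1 and 0.506 for 7 adipocyte markers and 0, 0 and 0.47 for 9 haematopoietic niche factors. They were 2, 2 and 0.139 for 22 collagens and extracellular matrix genes, 1, 3 and 0.139 for 12 contractile genes, 0, 0 and 0.613 for 24 cell cycle genes and 1, 3 and 0.219 for 14 NF-kB targets. For 17 hypoxia and glycolysis genes they were 2, 2 and 0.15, for 21 oxidative phosphorylation genes 0, 0 and 0.409, for 22 ribosomal protein genes 1, 0 and 0.668 and for 10 housekeeping genes 0, 0 and 0.606. The 14 immediate early and heat shock genes gave 2, 3 and 0.229, and the 12 p53 targets 3, 0 and 0.336. Lists with under 4 measured members were counted only: 0 of 3 chondrocyte markers and 0 of 1 B cell marker changed, 1 of 2 endothelial markers rose and 1 fell, 2 of 3 epithelial markers rose and 1 fell, and 1 of 3 osteoclast markers fell. No T and NK cell or skeletal muscle marker passed the filter. Over the 11061 genes expressed in NC, 538 genes were called and 54.6% of them were higher in BM, against 35.7% of the 1280.

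Libraries of GFP-sorted cells from the marrow of mice given stromal cells alone differed from those of the cultured cells first in blood-cell genes. S100a8 rose from 0.577 ± 0.208 to 834 ± 191 FPKM (log2 10.37 ± 0.26), a gene chosen after its values were seen. Cybb, the phagocyte oxidase subunit, was at least 3862-fold higher at 19.4 ± 6.62 FPKM in HOMING with 0 counts in NC. Leukocyte receptor genes Pirb and Cd300lf and the lymphocyte antigen gene Cd52 also had 0 counts in NC and were at least 1931-fold, 1791-fold and 1188-fold higher, and Slc4a1, with 0 counts in NC as well, was at least 1583-fold higher. These bounds set a floor of 3 counts over the NC group and cover counting error only. Hbb-bs rose from 0.0733 ± 0.0808 to 923 ± 251 FPKM (log2 13.35 ± 0.36), and without NC replicate 3 its log2 change was 14.28. Of 1765 called genes, 1187 were higher and 578 lower in HOMING, while over the 11061 genes expressed in NC, a set that leaves out genes low in NC and so mainly rises, 474 were higher and 514 lower.

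The largest falls were in genes of varied function. Cdsn, which encodes the adhesion protein corneodesmosin, fell from 116 ± 17.2 to 10.9 ± 0.767 FPKM (log2 -3.53 ± 0.11). The teneurin gene Tenm4 fell from 6.92 ± 0.603 to 0.583 ± 0.00577 FPKM (log2 -3.68 ± 0.14), the ATP-gated channel gene P2rx3 fell from 6.80 ± 2.55 to 0.537 ± 0.0231 FPKM (log2 -3.59 ± 0.22), the aldo-keto reductase gene Akr1b7 fell from 5.86 ± 1.497 to 0.450 ± 0.0265 FPKM (log2 -3.81 ± 0.21) and Prr32, which encodes a proline-rich protein, fell from 6.84 ± 0.655 to 0.287 ± 0.0737 FPKM (log2 -4.67 ± 0.22). The connexin gene Gjb2 fell from 5.39 ± 4.76 to 0.377 ± 0.0751 FPKM (log2 -3.96 ± 0.56) with most of its NC signal in replicate 3 (10.8 FPKM): without NC replicate 3 its log2 change was -2.93. Adjusted p over the 12 genes named by the rule ranged from 2.38e-11 to 3.51e-05 in edgeR.

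Blood-cell lists rose as a whole. The neutrophil list had 16 of 16 members higher (camera adjusted p 3.83e-09), the macrophage list 11 of 12 (camera adjusted p 3.10e-06), the erythroid list 6 of 6 (camera adjusted p 0.000196) and the megakaryocyte list 4 of 5 (camera adjusted p 0.00522), with 0 lower in each. Beside them the interferon response rose with 20 of 20 genes (camera adjusted p 1.62e-09), antigen presentation with 10 of 13 (camera adjusted p 7.36e-05) and migration receptors and integrins with 9 of 14 higher and 1 lower (camera adjusted p 0.00181). The interferon-induced transcription factor Irf7 rose from 0.517 ± 0.147 to 33.1 ± 7.34 FPKM (log2 5.89 ± 0.21), and Tap1 rose from 0.710 ± 0.159 to 11.9 ± 2.92 FPKM (log2 3.95 ± 0.20). With the correlation estimated from the data, the adjusted p over these 7 lists was 0.266 to 0.409. Over the 11061 genes expressed in NC the migration and integrin list was not called (adjusted p 0.809). HOMING replicate 3 held more of the blood markers, at a median of 1.52 times the mean of replicates 1 and 2 over 39 genes.

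Cytokine and suppressor lists also rose. Of the myeloid-recruiting genes 10 of 19 rose and 1 fell (camera adjusted p 0.00141): Il1b rose from 0.0800 ± 0.0265 to 87.4 ± 24.5 FPKM (log2 9.95 ± 0.30) and Ccl3 rose from 0.240 ± 0.108 to 271 ± 76.6 FPKM (log2 10.01 ± 0.30), both monocyte products. Of the immunosuppressive mediators 8 of 14 rose and 0 fell (camera adjusted p 0.00406), among them Cd274, which encodes the checkpoint ligand PD-L1 and rose from 0.450 ± 0.118 to 20.6 ± 4.84 FPKM (log2 5.41 ± 0.20), and the nitric oxide synthase gene Nos2, which rose from 4.64 ± 0.923 to 33.3 ± 3.75 FPKM (log2 2.73 ± 0.13). Of the NF-kB targets 10 of 14 rose and 1 fell (camera adjusted p 0.00806), and among cell cycle genes 2 of 24 rose (camera adjusted p 0.00746): Mki67 rose from 23.2 ± 0.458 to 72.7 ± 3.29 FPKM (log2 1.54 ± 0.05) and Aurkb rose from 13.7 ± 0.426 to 57.7 ± 0.743 FPKM (log2 1.97 ± 0.06). An estimated correlation gave these 4 lists adjusted p of 0.348 to 0.579. Over the 11061 genes expressed in NC the myeloid-recruiting and immunosuppressive lists were not called.

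The unfolded protein response and matrix lists moved down in HOMING. Of the unfolded protein response genes 1 of 13 rose and 8 fell (camera adjusted p 0.00017): Chac1 fell from 201 ± 15 to 24.0 ± 1.17 FPKM (log2 -3.18 ± 0.09) and Trib3 fell from 101 ± 4.92 to 18.0 ± 0.642 FPKM (log2 -2.60 ± 0.07). Of the collagens and extracellular matrix genes 2 of 22 rose and 6 fell (camera adjusted p 0.00806), led by fibronectin, where Fn1 fell from 573 ± 9.13 to 153 ± 2.64 FPKM (log2 -2.02 ± 0.08), and by the collagen gene Col5a2, which fell from 68.6 ± 7.36 to 24.6 ± 0.616 FPKM (log2 -1.60 ± 0.08). Adjusted p over these 2 lists was 0.169 to 0.573 once the correlation was estimated. Adjusted over the list alone, each list gave the same counts as over all genes. The other tested lists were not called.

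Libraries of GFP-sorted cells from the injection site held RNA of genes close to 0 in the cultured cells and more RNA of hypoxia genes. The purity of the sort is not given, so this RNA may not all come from the marked cells. Rhox5 (Entrez 18617) rose from 0.133 ± 0.119 to 185 ± 71.9 FPKM (log2 10.24 ± 0.40), and the simple-epithelium keratin Krt8 (Entrez 16691) rose from 0.0767 ± 0.0643 to 64.6 ± 25.3 FPKM (log2 9.59 ± 0.41). Egln3 (Entrez 112407), the oxygen-sensing prolyl hydroxylase induced by low oxygen, rose from 1.77 ± 0.325 to 152 ± 54.7 FPKM (log2 6.31 ± 0.25). The cytokine Il6 fell from 13.3 ± 2.80 to 1.81 ± 0.140 FPKM (log2 -3.00 ± 0.19). Egln3 and Il6 were chosen after their values were seen. Of 2019 called genes, 1200 were higher and 819 lower in TUMOR, and over the 11061 genes expressed in NC, again without genes low in NC, 728 were higher and 708 lower.

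Among the other large rises, Rhox2d rose from 0.0433 ± 0.0379 to 28.6 ± 9.80 FPKM (log2 9.22 ± 0.41) from 4 counts over NC. The Y-linked translation factor Eif2s3y had 1179 counts in TUMOR and 1 in NC, a ratio of 1138 (95% interval of the counts 204 to 44980). The homeobox gene Hoxd9 had 2014 against 2 counts, a ratio of 972 (269 to 8031), and the membrane gene Tmem37 801 against 1, a ratio of 773 (138 to 30570). These intervals cover counting error only. Of the falls, Ptx3, which encodes the secreted pentraxin 3, fell from 676 ± 111 to 39.1 ± 6.41 FPKM (log2 -4.24 ± 0.13). The cysteine synthesis gene Cth fell from 91.7 ± 3.78 to 7.26 ± 0.915 FPKM (log2 -3.78 ± 0.08), the metalloreductase gene Steap4 fell from 8.55 ± 3.33 to 0.707 ± 0.0666 FPKM (log2 -3.71 ± 0.24), and Prr32 and Akr1b7 fell by 4.74 ± 0.23 and 3.54 ± 0.21 on the log2 scale. Gjb2 fell by 3.99 ± 0.56, and by 2.96 without NC replicate 3. Without NC replicate 1 the log2 changes of Rhox5 and Krt8 were 11.19 and 10.55 and no count remained for Hoxd9 and Tmem37, nor for Eif2s3y without NC replicate 2. Adjusted p over the 12 genes named by the rule ranged from 5.85e-12 to 3e-05 in edgeR.

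Krt8 and Rhox2d belonged to a set of 40 genes, chosen after their values were seen, with at most 0.1 FPKM in NC and at least 3 FPKM in TUMOR. Over this set the median level in BM was 19% of that in TUMOR, and in HOMING it was 3.1%. TUMOR replicate 1 held more of it than replicates 2 and 3, at a median ratio of 1.78.

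Hypoxia and glycolysis genes rose, with 11 of 17 higher and 0 lower (camera adjusted p 6.17e-06). The vasodilator peptide gene Adm rose from 0.137 ± 0.0764 to 69.4 ± 27.6 FPKM (log2 8.88 ± 0.38), the glycolytic enzyme gene Pfkp rose from 4.13 ± 0.575 to 40.6 ± 8.60 FPKM (log2 3.18 ± 0.14) and the pyruvate dehydrogenase kinase gene Pdk1 rose from 9.76 ± 0.781 to 40.1 ± 4.37 FPKM (log2 1.92 ± 0.08). The 11 risers had a median ratio of TUMOR replicate 1 to replicates 2 and 3 of 1.16 (range 1.06 to 1.89). None is in the set of 40, whose limit of 0.1 FPKM in NC leaves out genes expressed in culture. RNA already present in NC lowers this ratio, so it does not tell sources of the rise apart. Egln3 (152 ± 54.7 FPKM) and Adm varied between TUMOR libraries about as widely as Krt8 (64.6 ± 25.3 FPKM), and Pfkp and Pdk1 varied less. Of the unfolded protein response genes 1 of 13 rose and 7 fell (camera adjusted p 0.00391): Chac1 fell from 201 ± 15 to 22.0 ± 2.58 FPKM (log2 -3.31 ± 0.09) and Asns fell from 267 ± 2.50 to 93.1 ± 1.09 FPKM (log2 -1.64 ± 0.04). Cell cycle genes gave 4 risers and 1 faller of 24 (camera adjusted p 0.00173), with Mki67 rising from 23.2 ± 0.458 to 89.1 ± 1.83 FPKM (log2 1.82 ± 0.05) and Aurkb rising from 13.7 ± 0.426 to 65.3 ± 4.25 FPKM (log2 2.13 ± 0.06). For these 3 lists the estimated correlation gave adjusted p of 0.239 to 0.409.

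**Figure D4:**
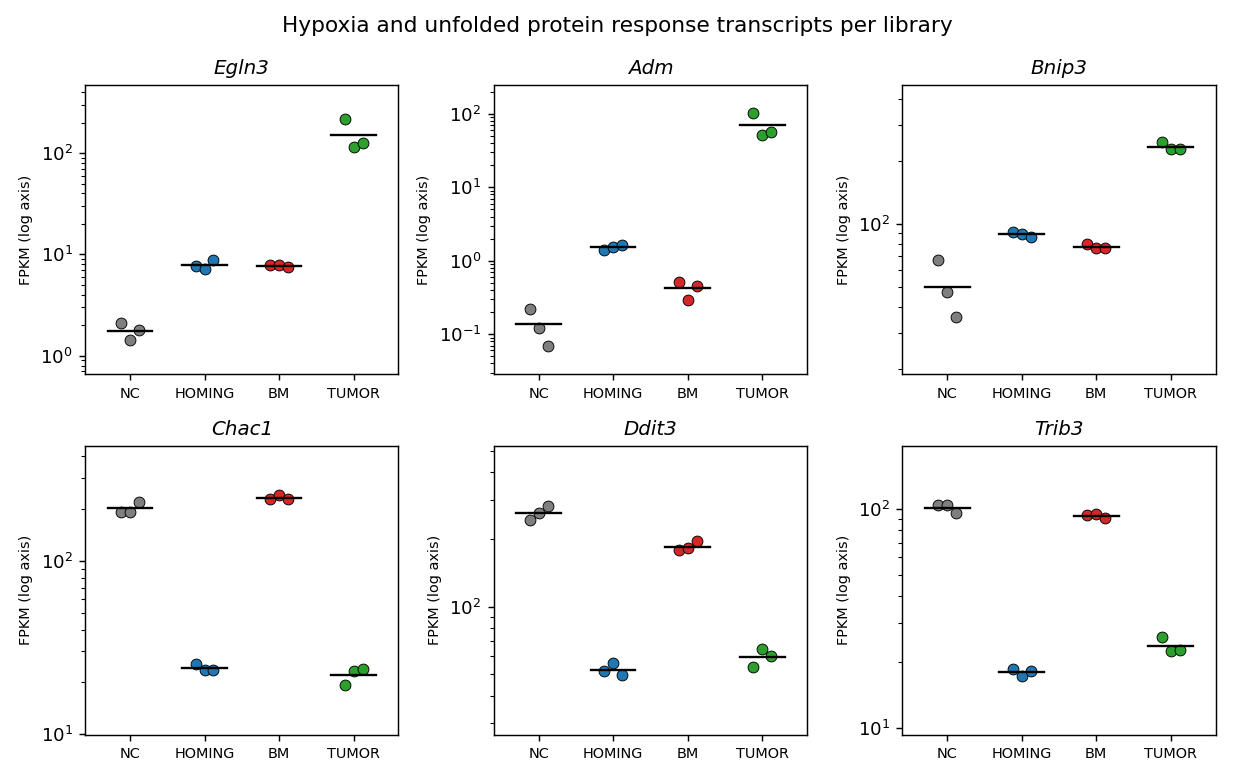
FPKM on a log axis in each of the 12 libraries for the hypoxia genes Egln3, Adm and Bnip3 and the unfolded protein response genes Chac1, Ddit3 and Trib3, by group on the x axis. Points are libraries and lines are group means, with the hypoxia genes highest in TUMOR and the others lower in HOMING and TUMOR than in NC and BM.

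The myeloid-recruiting list moved down at the injection site: 2 of 19 rose and 8 fell (camera adjusted p 0.0488), a call that ended without NC replicate 3 (adjusted p 0.0682), without TUMOR replicate 1 (0.0514) and without TUMOR replicate 3 (0.0585). Ccl2 fell from 795 ± 45.6 to 401 ± 54.9 FPKM (log2 -1.11 ± 0.08), Ccl7 fell from 96.2 ± 13.0 to 44.5 ± 7.54 FPKM (log2 -1.24 ± 0.11), and the macrophage growth factor Csf1 fell from 272 ± 33.1 to 87.1 ± 5.20 FPKM (log2 -1.75 ± 0.08). With an estimated correlation its adjusted p was 0.656. Blood-cell lists were not called: of 16 neutrophil markers 2 rose and 2 fell (1 and 2 adjusted over the list alone), of 12 macrophage markers 2 rose and 1 fell, and of 6 erythroid markers 2 rose (0 adjusted over the list alone). In the other lists the counts adjusted over the list alone were the same.

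In mice given both cell types, libraries of GFP-sorted cells from the marrow exceeded those from the injection site in inflammatory cytokines and fell short in hypoxia genes. Il1b rose from 0.0300 ± 0.0265 to 11.9 ± 0.286 FPKM (log2 8.57 ± 0.39), Ccl3 rose from 0.177 ± 0.153 to 31.9 ± 0.748 FPKM (log2 7.49 ± 0.35) and Csf3 rose from 0.0433 ± 0.0252 to 6.11 ± 0.569 FPKM (log2 7.17 ± 0.41). The innate immune receptor gene Clec4e rose from 0.0133 ± 0.00577 to 5.32 ± 0.127 FPKM (log2 8.65 ± 0.38) and the interleukin 36 gene Il1f6 rose from 0.0400 ± 0.0173 to 8.14 ± 0.741 FPKM (log2 7.63 ± 0.39), while Wfdc17 had 362 counts in BM and 1 in TUMOR, a ratio of 362 (95% interval of the counts 64.5 to 14320). Adm fell from 69.4 ± 27.6 to 0.420 ± 0.115 FPKM (log2 -7.32 ± 0.33) and Egln3 fell from 152 ± 54.7 to 7.76 ± 0.186 FPKM (log2 -4.26 ± 0.22). Il1b, Ccl3 and Csf3 were higher still in HOMING, as the blood markers were, while Il6 and Ccl2 had their highest means in BM. Whether blood-cell RNA in BM was a source of Il1b, Ccl3 and Csf3 was not tested. Of 1752 called genes, 896 were higher and 856 lower in BM.

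Other falls included the keratin Krt19, which fell from 21.6 ± 0.728 to 0.370 ± 0.0520 FPKM (log2 -5.76 ± 0.27), the placental growth factor gene Pgf, which fell from 7.33 ± 2.50 to 0.153 ± 0.0493 FPKM (log2 -5.55 ± 0.36), the selenium-binding gene Selenbp1, which fell from 31.7 ± 6.58 to 0.677 ± 0.176 FPKM (log2 -5.50 ± 0.20), and the sphingolipid transporter gene Spns2, which fell from 6.57 ± 2.42 to 0.190 ± 0.0557 FPKM (log2 -5.08 ± 0.28). Adjusted p over the 12 genes named by the rule ranged from 5.47e-10 to 7.95e-08 in edgeR. The risers rested on few TUMOR counts: without TUMOR replicate 1 the log2 changes of Il1b and Ccl3 were 9.26 and 8.40 and no TUMOR count remained for Wfdc17, and without TUMOR replicate 2 that of Csf3 was 7.76.

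Myeloid-recruiting genes rose in BM, 16 of 19 higher and 0 lower (camera adjusted p 5.80e-08): Ccl2 rose from 401 ± 54.9 to 2412 ± 127 FPKM (log2 2.62 ± 0.08), and Il6 rose from 1.81 ± 0.140 to 32.4 ± 2.40 FPKM (log2 4.21 ± 0.19). NF-kB targets rose with 11 of 14 (camera adjusted p 6.52e-06), led by the superoxide dismutase gene Sod2, which rose from 24.2 ± 0.918 to 135 ± 5.23 FPKM (log2 2.53 ± 0.10). Matrix proteases rose with 7 of 19 (camera adjusted p 0.00113), among them Mmp3 from 19.96 ± 4.65 to 310.2 ± 9.88 FPKM (log2 4.00 ± 0.16) and Mmp13 from 1.68 ± 0.104 to 33.5 ± 1.25 FPKM (log2 4.36 ± 0.21). Of the unfolded protein response genes 5 of 13 rose and 1 fell (camera adjusted p 0.00635), and of the immediate early and heat shock genes 6 of 14 rose and 2 fell (camera adjusted p 0.0164), with Atf3 rising from 10.7 ± 0.308 to 97.3 ± 1.04 FPKM (log2 3.22 ± 0.08). Hypoxia and glycolysis genes fell, 7 of 17 lower and 0 higher (camera adjusted p 8.31e-06). An estimated correlation gave these 6 lists adjusted p of 0.239 to 0.656.

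Blood markers were higher in BM than in TUMOR as well: 12 of 16 neutrophil markers rose (camera adjusted p 0.000114), 10 of 12 macrophage markers rose (camera adjusted p 0.00181) and 8 of 14 migration receptors and integrins rose (camera adjusted p 0.0197), with 0 lower in each. Adjusted p over these 3 lists was 0.409 to 0.416 once the correlation was estimated. Counts adjusted over the list alone were the same in each list. Over the 11061 genes expressed in NC, 541 were higher and 481 lower in BM than in TUMOR, and the migration and integrin list was not called (adjusted p 0.497).

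Against the cultured cells, BM showed the inflammatory genes together with a weaker blood signature than HOMING. Il1b rose from 0.0800 ± 0.0265 to 11.9 ± 0.286 FPKM (log2 7.10 ± 0.34), Mmp12 rose from 0.0400 ± 0.010 to 7.42 ± 0.243 FPKM (log2 7.46 ± 0.30) and Rhox5 rose from 0.133 ± 0.119 to 43.6 ± 0.615 FPKM (log2 8.20 ± 0.43). The Fc receptor chain gene Fcer1g had 808 counts in BM and 3 in NC, a ratio of 259.7 (95% interval of the counts 88.5 to 1262). Among the falls, Ccn5 fell from 7.87 ± 0.475 to 0.743 ± 0.0907 FPKM (log2 -3.48 ± 0.14) and Pla2g2e fell from 10.5 ± 1.90 to 1.14 ± 0.0513 FPKM (log2 -3.26 ± 0.17); these encode a matricellular growth factor and a secreted phospholipase. Il1b was higher still in HOMING, as the blood markers were. Of 1416 called genes, 977 were higher and 439 lower in BM. Without NC replicate 1 the log2 change of Rhox5 was 9.15, and without NC replicate 3 that of Fcer1g was 8.72.

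Camera called 13 lists in BM against NC. Myeloid-recruiting genes had 14 higher and 1 lower of 19 (camera adjusted p 7.81e-06), NF-kB targets 9 higher and 0 lower of 14 (camera adjusted p 5.27e-05), immunosuppressive mediators 7 higher and 0 lower of 14 (camera adjusted p 0.0197) and immediate early and heat shock genes 3 higher and 0 lower of 14 (camera adjusted p 0.0169). Neutrophil markers had 11 higher and 0 lower of 16 (camera adjusted p 8.70e-05), with 12 higher adjusted over the list alone, macrophage markers 9 higher and 0 lower of 12 (camera adjusted p 0.00104) and migration receptors and integrins 9 higher and 0 lower of 14 (camera adjusted p 0.0169). Antigen presentation had 6 higher and 1 lower of 13 (camera adjusted p 0.046), a call that ended without BM replicate 3 (adjusted p 0.051), NC replicate 2 (0.0502) or NC replicate 3 (0.104). Contractile genes moved down with 1 higher and 6 lower of 12 (camera adjusted p 0.00166), and so did collagens and extracellular matrix genes with 1 higher and 5 lower of 22 (camera adjusted p 0.0169), where the call ended without NC replicate 3 (adjusted p 0.076). Oxidative phosphorylation genes moved down with 0 higher and 0 lower of 21 (camera adjusted p 0.00406), cell cycle genes up with 1 higher and 0 lower of 24 (camera adjusted p 0.00297) and hypoxia genes up with 1 higher and 0 lower of 17 (camera adjusted p 0.00598). For these 13 lists the estimated correlation gave adjusted p of 0.306 to 0.703. In the other lists the counts adjusted over the list alone were the same, and over the 11061 genes expressed in NC 373 were higher and 370 lower. Over these genes the migration and integrin list (adjusted p 0.809), immunosuppressive mediators and antigen presentation were not called.

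TUMOR against HOMING set the injection site against the marrow of mice given stromal cells alone. Krt8 rose from 1.38 ± 0.247 to 64.6 ± 25.3 FPKM (log2 5.54 ± 0.28), the homeobox gene Hoxd8 rose from 0.177 ± 0.0586 to 8.28 ± 2.31 FPKM (log2 5.58 ± 0.29) and the transcription factor Tfap2a rose from 0.0867 ± 0.0306 to 5.46 ± 2.09 FPKM (log2 5.99 ± 0.36). Beta-globin Hbb-bt had 0 counts in TUMOR and was at least 3509-fold lower, and the immune cell genes Nfam1, Slamf7 and Adgre1 were at least 1096-fold, 1049-fold and 1002-fold lower. Of 1329 called genes, 544 were higher and 785 lower in TUMOR, while over the 11061 genes expressed in NC 279 were higher and 262 lower, and the migration and integrin list was not called (adjusted p 0.827).

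Camera called 13 lists in TUMOR against HOMING. Hypoxia and glycolysis genes rose with 10 higher and 0 lower of 17 (camera adjusted p 1.50e-10). Blood markers fell, with 0 higher and 16 lower of 16 (camera adjusted p 3.65e-13) for the neutrophil list, 0 higher and 12 lower of 12 (camera adjusted p 1.62e-09) for the macrophage list, 0 higher and 6 lower of 6 (camera adjusted p 6.17e-06) for the erythroid list and 0 higher and 5 lower of 5 (camera adjusted p 0.00104) for the megakaryocyte list. The interferon response had 0 higher and 19 lower of 20 (camera adjusted p 2.58e-13), myeloid-recruiting genes 0 higher and 16 lower of 19 (camera adjusted p 5.68e-09), immunosuppressive mediators 0 higher and 8 lower of 14 (camera adjusted p 0.000196) and NF-kB targets 0 higher and 9 lower of 14 (camera adjusted p 5.64e-06), the last with 1 higher and 9 lower adjusted over the list alone. Antigen presentation had 0 higher and 7 lower of 13 (camera adjusted p 3.30e-05) and migration receptors and integrins 0 higher and 9 lower of 14 (camera adjusted p 0.000177). Osteoblast markers moved up with 1 higher and 0 lower of 6 (camera adjusted p 0.0285). Collagens and extracellular matrix genes moved up with 4 higher and 4 lower of 22 (camera adjusted p 0.0415), a call that ended without HOMING replicate 3 (adjusted p 0.0531), TUMOR replicate 2 (0.0854) or TUMOR replicate 3 (0.0867). With the correlation estimated from the data, the adjusted p over these 13 lists was 0.239 to 0.656. In the other lists the counts adjusted over the list alone were the same.

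Libraries of all 3 recovered groups shared 492 genes that changed in the same direction against NC, 342 higher and 150 lower. The balance turned over the 11061 genes expressed in NC, a filter that takes out mainly rises, with 107 higher and 135 lower, under limma with quantile normalization, with 57 and 90, and without a minimum fold change, with 2264 and 2322. Independent lists of these sizes would share 9.2 and 1.4 genes. Part of the excess may come from the 3 NC libraries, which the 3 comparisons share. Krt8 and Rhox5 were among the genes higher in each group, and Akr1b7 and Prr32 among those lower.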

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

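The tests in this part were chosen only after the result was seen. Single libraries that lie far from the others of their group of 3 were not tested.

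Kdm5d, Uty and Xist are sex-linked genes that did not pass the expression filter and were not used in the 6 comparisons. Kdm5d, on the Y chromosome, had 176 counts over the HOMING libraries, 117 over BM and 485 over TUMOR, against 0 over NC. Uty, on the same chromosome, had 121 counts over HOMING, 105 over BM and 372 over TUMOR, against 0 over NC. Xist, which is transcribed from the inactive X chromosome, had 521 counts over BM against 66 over NC, 64 over HOMING and 81 over TUMOR. The sex of the animals and of the cells is not given in the sources used here.

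Blood-cell genes were higher in HOMING than in NC. The 4 blood-cell lists had 94.9% of their markers called higher, 16 of 16 for neutrophils, 11 of 12 for macrophages, 6 of 6 for red cells and 4 of 5 for megakaryocytes. Among the 3 most abundant, Hba-a1 and S100a8 reached 1250.0 and 834 FPKM in HOMING against 0.230 and 0.577 FPKM in NC, and of the 39 markers 7 had a mean of at least 1 FPKM in NC and 0 belong to another list. The log2 ratio of HOMING replicate 3 to replicates 1 and 2 had an SD of 0.189 over the markers (median 0.61). Over 410 other genes called higher and expressed in NC the SD was 0.246 (median 0.13). The SD ratio of 0.768 does not decide between RNA of marrow blood cells in the samples and induction in the injected cells. Counts of 4 Y-linked genes summed to at most 3 in an NC library and to 361, 344 and 545 in HOMING replicates 1, 2 and 3. Like the markers, they were highest in replicate 3. They argue against induction in the injected cells for these 4 genes and do not cover the blood markers. If the injected cells were like those of NC, HOMING thus held RNA from outside the injected cells. For the markers both stay open. The labels name a sort for GFP cells, which is meant to remove unmarked blood cells, but no gate or purity.

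A set of 40 genes that includes Krt8 and Rhox2d, with at most 0.1 FPKM in NC and at least 3 FPKM in TUMOR, was raised in TUMOR. The log2 ratio of TUMOR replicate 1 to replicates 2 and 3 had an SD of 0.117 over the set (median 0.83). It was 0.292 over the 720 other genes with an Entrez number called higher at a mean of at least 3 FPKM in TUMOR (median 0.21). The ratio of 0.4 between the SDs does not decide whether RNA of a second cell population in the TUMOR samples accounts for the rise. RNA already present in NC lowers and spreads the ratio of the other genes, and the set was chosen without such RNA. An induction shared by the set and stronger in replicate 1 could give the same SD. Induction in the injected cells is argued against for the Y-linked part, since 4 Y-linked genes summed to at most 3 counts in an NC library and to 800 to 1463 counts in a TUMOR library. Within TUMOR these counts moved with the set, at 1463 in replicate 1 and 800 and 808 in replicates 2 and 3, and Eif2s3y is 1 of the 40 genes. Across groups their totals of 1250 counts over HOMING, 859 over BM and 3071 over TUMOR do not follow the set. Its median level was 3.1% of TUMOR in HOMING and 19% in BM. The Y-linked counts thus do not settle induction for the other genes. Induction of the other genes, the tumour line as the second population and RNA or reads crossing between samples were not tested and stay open, as does the source of the signal in HOMING, where mice received stromal cells alone.

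Of the 19 measured myeloid-recruiting genes, 8 had their highest mean in BM and an adjusted p under 0.05 against HOMING (Cxcl1, Cxcl5, Csf2, Il6, Ccl2, Ccl7, Lif and Vegfa), with a median log2 change of 1.00 against HOMING and 4 of them called. RNA of marrow blood cells in BM as the source of the rise over HOMING is argued against by the 39 blood markers, whose median log2 change from HOMING to BM was -4.00. Blood-cell RNA in BM is not excluded by this. Of the markers, 11 of 16 for neutrophils and 9 of 12 for macrophages were higher in BM than in NC, with 0 lower in both. The erythroid and megakaryocyte lists were not called there. Dilution of the HOMING samples by blood-cell RNA as the whole cause is argued against, since it would move 38 stromal and matrix genes alike and their median was 0.16 with an SD of 0.62, although 8 of them met the same rule at a median of 0.73 (range 0.28 to 1.58), so such a rise is not particular to the list. RNA of the second cell population is argued against for the 8 myeloid-recruiting genes alone, which were all lower in TUMOR than in NC at a median log2 change of -1.17. The rule that chose them, a highest mean in BM, already leaves out genes most abundant in TUMOR. A response of the marked cells to the tumour in the animal was not tested and stays open, as does dilution as a part of the rise.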

How the results depend on the processing

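Leaving out single libraries, the splits and the regroupings were planned, as were the other alternatives except DESeq2, limma on log2(FPKM + 1), scaling by library size and the restriction to genes expressed in NC, which were chosen after the data were seen.

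Counts of called genes stayed within 1.5 times those of the report under DESeq2, median-ratio or library-size scaling, limma with a pseudocount of 0.1 FPKM, the transcript with the highest mean FPKM, no variance trend, fits on the compared groups alone and the replicate block. With the replicate block 1285 genes were called in BM against HOMING, 1770 in HOMING against NC, 1421 in BM against NC, 2018 in TUMOR against NC, 1750 in BM against TUMOR and 1325 in TUMOR against HOMING. Replicate numbers do not pair the libraries: residuals of libraries with the same number correlated at -0.12 to 0.22, above 0.1 in 1 of 18 pairs, and those with other numbers at -0.15 to 0.20, above 0.1 in 3 of 36.

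Without a filter 21001 genes were tested in place of 12314, and 2579 genes were called in BM against HOMING, 3301 in HOMING against NC, 2536 in BM against NC, 3420 in TUMOR against NC, 3160 in BM against TUMOR, 2702 in TUMOR against HOMING and 805 against NC in all 3 recovered groups. Without a minimum fold change, which lets small changes pass, the counts in that order were 7158, 8617, 8198, 9068, 8576, 6776 and 4586. Limma on log2(FPKM + 1) called 855 in BM against HOMING (227 higher and 628 lower), 626 in BM against NC, 1301 in TUMOR against NC, 930 in BM against TUMOR and 165 in all 3 groups, and with quantile normalization the last 4 counts were 569, 1137, 901 and 147. Limma with a pseudocount of 0.1 FPKM called 1213, 1301, 1961, 1612 and 410 in the order given for log2(FPKM + 1). The lower counts there thus went with the pseudocount of 1 FPKM. Quantile normalization used values with that same pseudocount, and its own part was not tested. With 11061 genes tested, those expressed in NC, 538 were called in BM against HOMING, 988 in HOMING against NC, 743 in BM against NC, 1022 in BM against TUMOR, 541 in TUMOR against HOMING and 242 in all 3 groups, since genes silent in culture were left out.

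Leaving out 1 library gave 1276 to 1298 genes in BM against HOMING, 1737 to 1833 in HOMING against NC, 1373 to 1504 in BM against NC, 1853 to 2153 in TUMOR against NC, 1611 to 1819 in BM against TUMOR, 1209 to 1426 in TUMOR against HOMING, 458 to 520 in all 3 groups and 59 to 63 lists.

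Scaling by library size moved the median log2 change of all genes to 0.12 in HOMING against NC and 0.13 in TUMOR against NC, from 0.01 in each. The share of called genes that were higher went from 59.4% to 69.7% in TUMOR against NC under library-size scaling, and from 69% to 58.5% in BM against NC under quantile normalization. It was 51.1% in BM against TUMOR and turned under 50% without a filter (44.1%), without a minimum fold change (49.2%), with library-size scaling (47.9%) and under limma with a pseudocount of 0.1 (47.6%) or 1 FPKM (48.8%). Restricting to genes expressed in NC, which removes genes low in NC and so mainly those higher in the other groups, turned it from 67.3% to 48% in HOMING against NC, from 35.7% to 54.6% in BM against HOMING and from 40.9% to 51.6% in TUMOR against HOMING. Without a minimum fold change it was 50.4% in BM against HOMING and 50.6% in TUMOR against HOMING.

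Of the 61 list calls, 0 were made by camera with an estimated correlation, and fry called 109 of the 150 list tests. With genes expressed in NC alone 39 lists were called. There the migration receptors and integrins turned from a fall to a median log2 change of 0.081 in BM against HOMING (adjusted p 0.864, range over its 19 alternatives 2.06e-06 to 0.864), where Itgam and Selplg, under 1 FPKM in NC, were left out with others. Calls also ended there for that list in the 4 other comparisons that called it, where adjusted p ranged over the alternatives from 8.9e-08 to 0.809 in HOMING against NC, 1.02e-05 to 0.809 in BM against NC, 1.15e-05 to 0.497 in BM against TUMOR and 6.52e-08 to 0.827 in TUMOR against HOMING. They ended too for myeloid-recruiting genes in HOMING against NC (5.24e-07 to 0.416), immunosuppressive mediators in HOMING against NC (8e-08 to 0.348) and BM against NC (2.67e-06 to 0.416), and antigen presentation in BM against NC (0.000526 to 0.703). In BM against NC and BM against TUMOR the migration list was not called by limma on log2(FPKM + 1) or with quantile normalization either. Of the 61 lists, 51 stayed called under quantile normalization, 56 under limma on log2(FPKM + 1), and 59 to 61 under the other scalings, fits and filters. With genes expressed in NC alone 36 stayed called, 8 ended, 1 reversed and the other 16, of blood-cell lists, could not be tested.

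Of the 146 gene results named, 0 reversed under any setting. DESeq2 kept 145 on their side of the threshold, library-size scaling 144, limma on log2(FPKM + 1) 141, quantile normalization 142, and the setting with genes expressed in NC kept each of the 76 it could test. Depth limits genes near 0 in a group, where folds are bounds or carry wide counting intervals.

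For each comparison the 10 splits of the 6 libraries cannot give a share under 0.05. In each, 1 split, the real one, gave as many called genes. The real counts were 1280 in BM against HOMING, 1765 in HOMING against NC, 2019 in TUMOR against NC, 1752 in BM against TUMOR and 1329 in TUMOR against HOMING, with 0 genes as the highest other count, and 1416 in BM against NC, with 1. For the 492 genes shared by the 3 recovered groups 1 of 100 regroupings, the real one, gave as many (highest other 377). Replicates may be technical, which would favour the real one, so chance is not excluded. Nor is it for the lists called: 18 of 100 regroupings gave at least 61 (highest other 83, median of the others 43). Random groupings of these libraries thus often called many lists, so a list p-value of camera at the preset correlation is weak evidence by itself.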

Other observations

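Genes and lists in this part were chosen after their values were seen, and levels are mean FPKM ± SD (n = 3) in NC, HOMING, BM and TUMOR in that order. Of 14 amino acid synthesis and transport genes, 9 were called higher in BM than in HOMING, 12 lower in HOMING than in NC, 13 lower in TUMOR than in NC and 11 higher in BM than in TUMOR. Levels of Cth were 91.7 ± 3.78, 12.4 ± 0.373, 57.6 ± 3.59 and 7.26 ± 0.915, and those of the amino acid transporter gene Slc7a5 were 312 ± 16.7, 83.8 ± 2.44, 196 ± 1.85 and 83.1 ± 2.49.

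Of 8 targets of the oxidative stress regulator NRF2, 5 were called higher in HOMING than in NC, 5 higher in TUMOR than in NC and 2 lower in BM than in HOMING. Gsta1 stood at 6.88 ± 0.488, 62.0 ± 4.65, 8.28 ± 0.168 and 44.6 ± 8.03, and Nqo1 at 25.9 ± 3.25, 111 ± 6.89, 63.2 ± 0.322 and 92.6 ± 9.95.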
